A study of Mus musculus with 9 samples.

How the data were processed

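Gene expression was measured in mouse dendritic cells (DC) on 9 one-colour Affymetrix arrays, with total RNA labelled with biotin. Per the labels' protocols, the cells came from the spleens of mice carrying B16 melanoma tumours that secrete Flt3L, the growth factor that expands DC, and were purified on CD11c magnetic beads. The labels place 3 arrays each in an untreated, a TSA (trichostatin A) and a butyrate group. The labels give neither the dose nor the duration of either treatment, and they do not say whether the replicates of a group came from separate mice or cultures. The p-values therefore measure the spread between these samples only, which may be technical. Scan dates and hybridization batches were not analysed here.

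The deposited values are log2 expression levels of 22690 probe sets, made with RMA per the submitters' processing notes. RMA stands for background correction, quantile normalization and median polish over the probes of a set. The program, its version and the probe set definition are not given in the sources used here. The values ran from about 3 to 15 on every array with medians between 6.689 and 6.740, as log2 values would. RMA levels of dim genes lie close to a floor, so fold changes of such genes understate the change in RNA. The number of arrays, 3 per group, limits the precision.

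Probe sets were named through the platform annotation. Of the 22690 probe sets, 64 were Affymetrix controls, 20380 had 1 gene symbol, 691 had several and 1555 were unnamed here. The gene identifiers of 20351 probe sets matched the mouse reference gene table (GRCm38.p6), and this changed 0 symbols. Probe sets with several symbols or without a name entered no gene-level test. Each of the 12393 genes was represented by its probe set with the highest mean over the 9 arrays; 4956 genes had more than 1 probe set. No pair of arrays held identical values. Genes of the lists that have no row in this annotation are not analysed here.

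A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 3 groups shared 1 estimate of the spread per gene, with 6 residual and 3.9 prior degrees of freedom. The contrasts were TSA minus untreated, butyrate minus untreated and butyrate minus TSA. P-values were adjusted by the Benjamini-Hochberg method over the 12393 genes within a comparison, and a gene was called at an adjusted p under 0.05. A second threshold also asked for a change of at least 2-fold. Errors given after log2 fold changes are limma's standard errors with n = 3 arrays per group, and every adjusted p of a gene is limma's.

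The design, 30 gene lists and 11 lists of cell type markers were fixed before the data were examined, with 585 different symbols of which 505 were tested. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes, adjusted over the 41 lists of a comparison. The test was repeated with a correlation estimated for each list. For some lists that estimate lay below 0.01, so a call lost in this repeat need not reflect correlated genes. A further repeat used fry. It asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. Calls within a list were also counted after adjusting over the list alone. The named genes follow a rule fixed at the same time. It takes the 10 largest rises and 10 largest falls of each treatment (5 and 5 for butyrate against TSA) among called genes whose arrays did not overlap, leaving out predicted and clone-named genes, antigen receptor segments and olfactory or vomeronasal receptors. It adds up to 4 called members of each list with the largest changes, and a set of genes tied to DC activation, HDACs and butyrate sensing that are given whatever their value.

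Both treatments were compared with the same untreated arrays. The overlap and covariance of their changes are therefore given beside 100 simulations of unchanged groups that share 1 control group, and beside the overlap of independent lists of the same size. The script was tested on simulated data drawn from the real means and spreads of the 12393 genes, with 200 genes changed by known amounts. For TSA against untreated, 100% of 66 genes changed by 1 on the log2 scale were recovered, 91% of 67 changed by 0.5 and 29.9% of 67 changed by 0.25, with 9 false calls. For butyrate against untreated the shares were 100%, 85.1% and 32.8% with 7 false calls. For butyrate against TSA they were 100%, 89.6% and 26.9% with 10 false calls. Only 200 genes changed in these simulations, whereas the data called 47.3%, 58.4% and 35.9% of genes in the 3 comparisons. The adjusted threshold is easier to pass where more genes change, so the recovered shares do not carry over to the data. In a simulation of TSA against untreated over the 12393 genes, camera called the 1 list of the 41 that was shifted by 0.5 and 0 others. The simulated genes varied independently, so this does not show how camera behaves where genes of a list are correlated.

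Alternatives chosen in advance were a fit to only the 2 groups compared, the replicate number of the labels as a block, an intensity trend with robust variance estimation, 2 filters on dim genes (above the median or above the 25th percentile of level), the mean of a gene's probe sets, a test of every probe set, a further quantile normalization, equal array medians, array weights and leaving out each array in turn. After the data were seen, 2 scalings were added. They shift each array so that the mean of its hybridization spike-ins (7 probe sets of BioB, BioC and BioDn) or of its poly-A spike-ins (12 probe sets of Dap, Lys, Phe and Thr) is equal on all arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.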

Results

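The expression of 12393 genes was compared between Flt3L-elicited splenic dendritic cells (DC) left untreated and the same kind of cells treated with trichostatin A (TSA) or butyrate, with 3 arrays in each group. TSA is a hydroxamic acid and butyrate a short-chain fatty acid made by gut bacteria. Both inhibit histone deacetylases (HDACs), the enzymes that remove acetyl groups from histones, and the series asks how this inhibition changes gene expression in DC. Arrays of 1 group correlated with r between 0.9971 and 0.9985 across the 12393 genes. Untreated and TSA arrays correlated with r between 0.9739 and 0.9764, untreated and butyrate arrays between 0.9664 and 0.9686, and TSA and butyrate arrays between 0.9911 and 0.9934. These are correlations across genes, which are not independent replicates. The first principal component held 77.4% of the variance and the second 12.8%.

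With TSA, Il12b, the p40 subunit of interleukin 12 and interleukin 23, was 16-fold lower, the largest fall among the probe sets that represent genes here. Pdcd1lg2, which encodes the inhibitory ligand PD-L2, fell 13.6-fold, the NF-kB subunit Relb 4.71-fold and the lymph node homing receptor Ccr7 by 2.08 ± 0.047 on the log2 scale. All 16 measured genes of cholesterol biosynthesis and all 20 of the type I interferon response fell, while HDAC genes and several histone genes rose. In all, 3262 genes rose and 2604 fell with TSA, 47.3% of those tested, and 265 of the rises and 406 of the falls were at least 2-fold.

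Costimulatory and coinhibitory ligands did not move as 1 block. Of 13 measured genes, 2 rose, 7 fell and 4 were not called with TSA, or 2 and 8 adjusted over the list alone. Cd40, the receptor through which T cells license DC, was 2.83-fold lower, and Cd274 (PD-L1) fell by 1.67 ± 0.064 on the log2 scale. Cd86 rose slightly, by 0.28 ± 0.049, and Nectin2 rose by 1.72 ± 0.106 from a low level, whereas Cd80 was not called (0.12 ± 0.055, adjusted p = 0.114). A further probe set each of Cd86 and Cd80, tested over all probe sets, was higher with TSA by 0.53 (limma adjusted p = 6.59e-06) and 0.31 (0.0321). The remaining, dimmer Cd80 probe sets were not called (0.15 and 0.14, limma adjusted p = 0.204 and 0.219). The list lay below other genes by camera (adjusted p = 0.0124), a call lost with adjusted p = 0.116 with an estimated correlation. Of 10 genes that mark mature DC, 9 fell and 1 rose. Socs2 fell by 2.72 ± 0.051, Ccl22 by 2.66 ± 0.053 and Cd200 by 1.77 ± 0.059 (camera adjusted p = 3.63e-07, adjusted p = 0.0453 with an estimated correlation).

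Proinflammatory cytokines mostly fell or were not called. With TSA, 8 of 16 fell, 1 rose and 7 were not called, the same counts as adjusted over the list alone. Il6 fell by 1.74 ± 0.165, Il1b by 1.22 ± 0.055 and Il15 by 0.76 ± 0.068, while Tnf rose by 0.28 ± 0.084. The call of Tnf in TSA samples was lost on both spike-in scales (0.262 and 0.25) and without TSA replicate 1 (0.266) or TSA replicate 2 (0.263). The list's camera adjusted p was 0.0153, with adjusted p = 0.116 with an estimated correlation. Of the NF-kB subunits and feedback inhibitors, 14 of 15 fell and 1 rose (camera adjusted p = 3.88e-07, adjusted p = 0.0453 with an estimated correlation). Beside Relb (−2.24 ± 0.049), these included Traf1 (−1.40 ± 0.060), Bcl3 (−1.20 ± 0.054), Rel (−1.05 ± 0.061) and Rela (−0.64 ± 0.046). Among Toll-like receptors and their adaptors 11 of 16 fell and 1 rose, led by Tlr1 (−1.42 ± 0.053), Tlr7 (−1.41 ± 0.126), Irak1 (−1.35 ± 0.054) and the lipopolysaccharide coreceptor Cd14 (−1.33 ± 0.093), with a camera adjusted p of 2.92e-05 and adjusted p = 0.0453 with an estimated correlation. The 20 interferon-response genes that fell included the antiviral genes Rtp4 (−2.30 ± 0.127), Ifit3 (−2.23 ± 0.118) and Ifit1 (−2.20 ± 0.137). Their camera adjusted p was 5.37e-10, and the call was lost with adjusted p = 0.0996 with an estimated correlation.

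Chemokines and chemokine receptors fell with TSA in 11 of 17 and 8 of 13 genes, with 1 and 0 rising, and in 12 and 8 adjusted over the list alone. Among the chemokines of the list, the largest changes were in the T cell attractant Ccl22 (above), the neutrophil attractant Cxcl2 (−2.64 ± 0.069), Ccl17 (−2.10 ± 0.119) and Cxcl16 (−1.37 ± 0.043). Cxcl5 and Ppbp, other neutrophil attractants outside the list, were 13.1-fold and 10.4-fold lower; the level of Cxcl5 with TSA, 3.88, lies near the floor, so its fold is understated. The chemokine list kept no call with an estimated correlation (camera adjusted p = 2.91e-05, adjusted p = 0.0821 with an estimated correlation), and the receptor list did (0.000213 and 0.0453). Of 16 C-type lectin and Fc receptors 13 fell and 1 rose. Clec4n (dectin-2) fell 12.3-fold and Clec4d by 2.77 ± 0.084 on the log2 scale (camera adjusted p = 3.44e-06, adjusted p = 0.0453 with an estimated correlation).

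Of 10 genes of MHC class II presentation, 2 rose, 4 fell and 4 were not called with TSA, and the list did not differ from other genes (camera adjusted p = 0.441). H2-DMa, which loads peptides, rose by 0.83 ± 0.052, and its regulator H2-Oa by 0.51 ± 0.065. Ifi30 fell by 1.18 ± 0.045 and Ciita, the master regulator of class II genes, by 0.51 ± 0.045. Of 14 genes of class I presentation 7 fell and 0 rose, among them Tapbpl (−1.83 ± 0.060), Psmb10 (−1.59 ± 0.060) and Psme1 (−1.11 ± 0.056). The class I list had a camera adjusted p of 0.00124, lost with adjusted p = 0.127 with an estimated correlation.

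The largest rises with TSA were in genes of varied function. Abhd3, a phospholipase, rose 12.7-fold, Selenom 9-fold, the actin-binding gene Pfn2 6.06-fold, Maged1 5.74-fold, Armcx2 5.57-fold and the brain creatine kinase Ckb 5.25-fold. Csrp2, Fbxo2, Fgf11 and the mitochondrial isocitrate dehydrogenase Idh2 also rose at least 4-fold. Abhd3 and Selenom lay near the floor in untreated cells, at 4.63 and 4.29, so their folds are understated. Genes of HDACs themselves rose in 6 of 8 cases with 0 falling, led by Hdac6 (1.05 ± 0.062), Hdac1 (0.85 ± 0.052) and Hdac2 (0.66 ± 0.055). Their camera adjusted p was 0.00513, and adjusted p = 0.0697 with an estimated correlation. Of 7 genes on the histone list, 6 rose and 0 fell. The linker histone H1f2 rose by 2.17 ± 0.050, H2aw by 1.02 ± 0.055 and H2az2 by 0.98 ± 0.045 (camera adjusted p = 0.000474, adjusted p = 0.0453 with an estimated correlation). Of the sirtuins, HDACs of another class, 4 of 5 rose and Sirt1 fell by 1.02 ± 0.056 (camera adjusted p = 0.177).

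Metabolic genes split by pathway. In cholesterol biosynthesis all 16 genes fell with TSA, including Idi1 (−1.36 ± 0.044), Lss (−1.36 ± 0.071), Sc5d (−1.20 ± 0.058) and Cyp51 (−1.15 ± 0.055), with a camera adjusted p of 1.17e-10 and adjusted p = 0.0453 with an estimated correlation. Glycolysis genes rose in 9 of 12 cases and fell in 2, with Aldoc up by 1.35 ± 0.067, Tpi1 by 1.02 ± 0.071 and Pfkp by 0.94 ± 0.054 (camera adjusted p = 0.00513, adjusted p = 0.29 with an estimated correlation). Fatty acid oxidation and ketone genes rose in 10 of 18 cases and fell in 3, led by Hadh (1.92 ± 0.065), Bdh1 (1.87 ± 0.097) and Acaa2 (1.33 ± 0.069), with a camera adjusted p of 0.0183 and adjusted p = 0.224 with an estimated correlation. Heat shock genes rose in 9 of 13 cases and fell in 1. Hspa2 rose by 2.05 ± 0.084, Hspa1b by 0.97 ± 0.051 and Hspe1 by 0.95 ± 0.047 (camera adjusted p = 0.00286, adjusted p = 0.105 with an estimated correlation).

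Markers of cells that a CD11c selection can carry along also fell with TSA, beside the falls of the immune gene groups above. Of macrophage and monocyte markers 14 of 15 fell and 1 rose (median −0.61), of erythroid markers 8 of 8 fell (median −0.83), and of neutrophil markers 7 of 10 fell and 0 rose (median −0.67). B cell markers fell in 5 of 10 cases (median −0.28), T cell markers in 4 of 10 (−0.22) and NK cell markers in 4 of 8 (−0.20), with 0 rising in each list. Camera called these 6 lists and none kept the call with an estimated correlation, where adjusted p was 0.0996, 0.0865, 0.0697, 0.0865, 0.116 and 0.116. Of DC subset markers, 9 of 11 genes of CD11b-type DC and 6 of 8 of plasmacytoid DC fell with 0 rising, with adjusted p = 0.0453 with an estimated correlation for both lists. Of 10 genes of CD8-type DC 2 rose, 3 fell and 5 were not called (camera adjusted p = 0.398), or 3 and 3 adjusted over the list alone. The growth factor receptor Flt3 fell by 0.60 ± 0.045 and the CD11c gene Itgax by 0.99 ± 0.061. B16 melanoma markers stayed near the floor in most cases, with 1 of 9 rising and 2 falling, or 0 and 1 adjusted over the list alone. The difference between 3′ and 5′ probe sets of beta-actin, a sign of RNA integrity, was 0.432 ± 0.066 (SD, n = 3) log2 units in untreated, 0.641 ± 0.042 in TSA and 0.682 ± 0.040 in butyrate samples. For Gapdh it was 0.159 ± 0.014, 0.192 ± 0.025 and 0.224 ± 0.037. For the dimmer pyruvate carboxylase it moved the other way, by −0.357 with TSA and −0.834 with butyrate relative to untreated samples (exact two-sided permutation p = 0.1 each, the smallest possible).

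**Figure D1:**
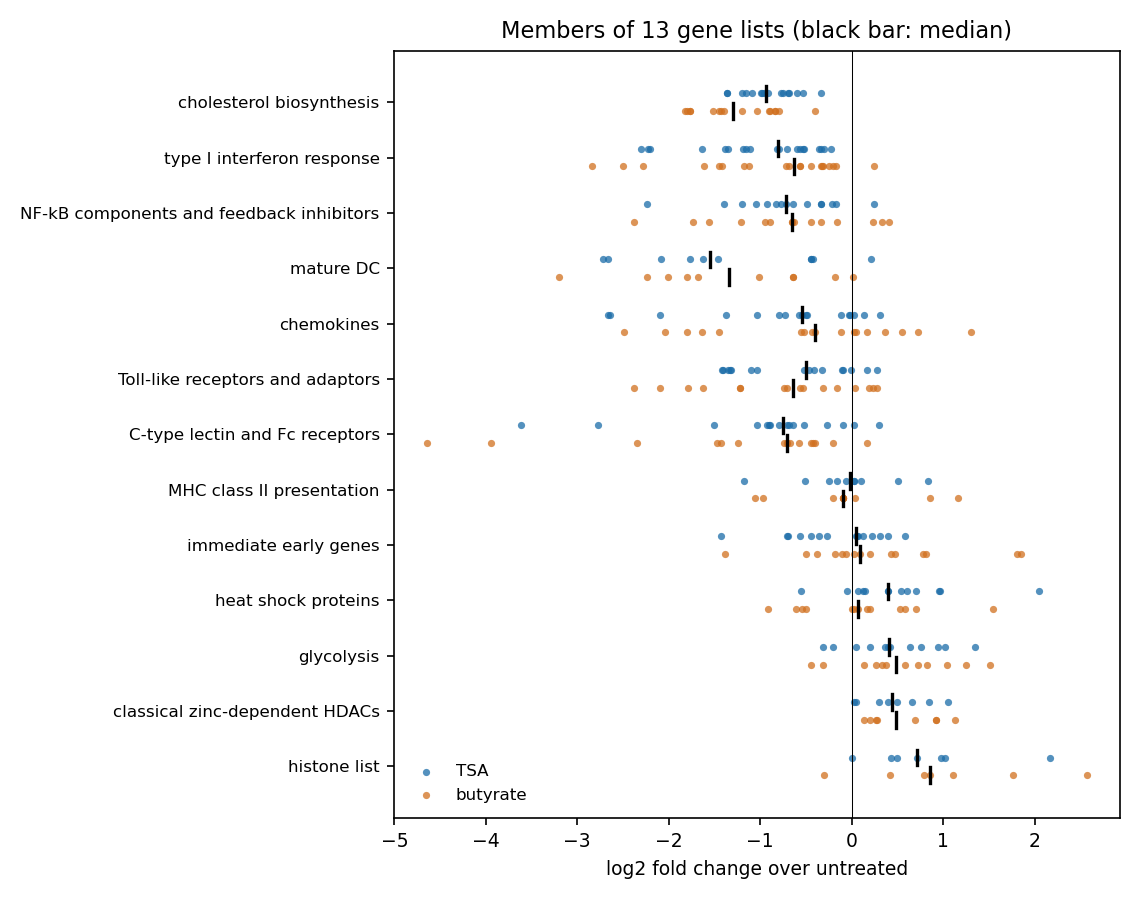
Log2 fold changes over untreated cells (x axis) of the measured members of 13 gene lists (y axis), with TSA in blue and butyrate in orange; each point is 1 gene and the black bar is the median of the list. Cholesterol genes lie below 0 with both treatments (medians −0.94 and −1.30) and HDAC genes above (0.45 and 0.48), but when arrays are scaled to hybridization spike-ins the butyrate median of HDAC genes falls to 0.068 and those of heat shock and immediate early genes (0.07 and 0.09) turn to −0.34 and −0.32.

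Shifting arrays to equal hybridization spike-ins, an alternative added after seeing the data, moved the median TSA change of all genes from 0.03 to 0.02 on the log2 scale and called 2685 genes higher and 2354 lower. With poly-A spike-ins, which varied more between arrays, 1180 were called higher and 1349 lower.

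With butyrate, the lipoprotein-associated phospholipase Pla2g7 was 29.9-fold lower (−4.90 ± 0.092), Clec4n 25-fold lower, Il12b 19.6-fold lower and the cystine transporter Slc7a11 17.8-fold lower. Relb fell 5.20-fold, and the interferon gene Ifit1, the cholesterol gene Cyp51 and the chemokine receptor Ccr7 fell by 2.50 ± 0.137, 1.82 ± 0.055 and 2.01 ± 0.047 on the log2 scale. Tnf moved the other way and was 1.95-fold higher. In all, 4166 genes rose and 3075 fell, 58.4% of those tested, with 339 of the rises and 570 of the falls at least 2-fold.

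The balance of rises and falls with butyrate depends on the scaling of the arrays and on the genes included. Bacterial and phage transcripts that are added to the sample as spike-ins were brighter on the butyrate arrays: the mean of 7 hybridization spike-in probe sets was 10.37 ± 0.08 (SD, n = 3) in untreated, 10.38 ± 0.03 in TSA and 10.78 ± 0.06 in butyrate samples, a difference of 0.415 ± 0.057 (SE) between butyrate and untreated. An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. Probe sets of the phage spike-in Cre, which that mean and the scaling leave out, rose by less with butyrate, from 0.148 to 0.194. Their group means of 14.253 to 15.045 lie near the highest values of the arrays (15.099 to 15.186). Whether this level limits their rise was not tested. A scaling to Cre was not tested. Scaling the arrays to equal hybridization spike-ins, an alternative added after seeing the data, moved the median change of all genes from 0.085 to −0.331, and the split of calls from 4166 up and 3075 down (57.5% up) to 932 up and 8417 down (10% up). With poly-A spike-ins it was 548 up and 3581 down (13.3% up). Such a shift lowers every butyrate value by about the same amount, and 594 of the 4166 rises were called as falls with the hybridization spike-ins. A filter on level, without rescaling, also moved the balance: among genes above the median level 2472 rose and 2513 fell (49.6% up). Values on the butyrate arrays were more compressed, with SDs of 2.244 to 2.259 against 2.284 to 2.317 on the other arrays. Their 25th percentiles were higher, at 5.069 to 5.093 against 4.971 to 5.025. Whether rises of dim genes with butyrate follow from this was not tested. A further quantile normalization, which makes the spread of arrays equal, gave 3775 up and 2946 down (56.2% up). Changes with butyrate are given below as the deposited scale has them, that is, relative to the bulk of genes. The hybridization scale lowers each of them by 0.415.

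**Figure D2:**
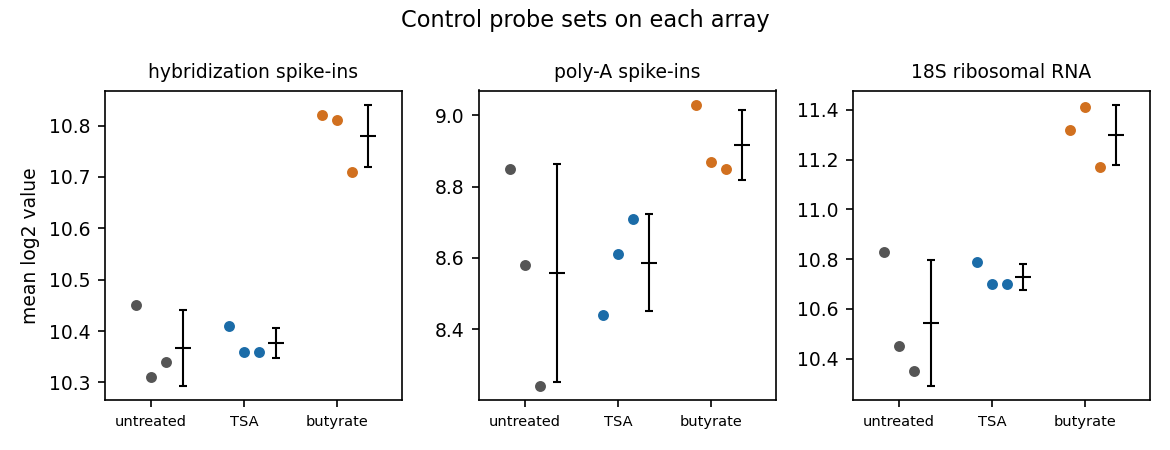
Mean log2 value of control probe sets (y axis) on each array, in untreated, TSA and butyrate samples (x axis), for 7 hybridization spike-in, 12 poly-A spike-in and 3 ribosomal RNA probe sets; points are arrays and the black marks are the mean ± SD (n = 3). Hybridization spike-ins on the 3 butyrate arrays lie between 10.71 and 10.82, above the 6 other arrays at 10.31 to 10.45.

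Among immune genes, Cd40 fell by 1.38 ± 0.053 with butyrate, Pdcd1lg2 by 3.77 ± 0.118 and Tnfsf4 (OX40 ligand) by 1.87 ± 0.147, and Cd274 was 2.83-fold lower. Nectin2 rose by 2.15 on the log2 scale. Of the 13 costimulatory and coinhibitory ligands 3 rose and 8 fell, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.0264, adjusted p = 0.193 with an estimated correlation). Cd80 was 0.18 ± 0.055 higher and turned to −0.231 on the hybridization spike-in scale, and Cd86 was not called (0.12 ± 0.049, adjusted p = 0.0614), although its other probe set, at nearly the same level, was 0.49 higher (limma adjusted p = 9.35e-06 over all probe sets). Of mature DC markers 9 of 10 fell and 0 rose, among them Socs2 (−3.20 ± 0.051) and Cd200 (−2.24 ± 0.059), with a camera adjusted p of 7.82e-07 and adjusted p = 0.0652 with an estimated correlation. NF-kB genes fell in 12 of 15 cases and rose in 3, with Rel at −1.74 ± 0.061 and Traf1 at −1.56 ± 0.060 (camera adjusted p = 0.000239, adjusted p = 0.125 with an estimated correlation). Of 20 interferon-response genes 17 fell and 1 rose, or 18 and 1 adjusted over the list alone. Rtp4 fell by 2.84 ± 0.127 and Ifih1, an RNA sensor, by 1.61 ± 0.048 (camera adjusted p = 7.82e-07, adjusted p = 0.197 with an estimated correlation). Toll-like receptors and adaptors fell in 12 of 16 cases and rose in 2, with Cd14 at −2.38 ± 0.093 and Tlr1 at −2.10 ± 0.053 (0.000107 by camera, adjusted p = 0.0652 with an estimated correlation).

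Proinflammatory cytokines rose in 5 and fell in 5 of 16 cases with butyrate, and camera did not call the list (adjusted p = 0.217). On the hybridization spike-in scale 1 rose and 11 fell, and on the poly-A spike-in scale 1 rose and 7 fell. Il6 fell by 2.09 ± 0.165 and Il1b by 1.02 ± 0.055, while Tnf rose by 0.96 ± 0.084. Il12a and Il10 were not called (−0.25 ± 0.111 and −0.20 ± 0.089). Il10 averaged 4.02 over all arrays, near the floor, so its lack of a call says little about its RNA. Among chemokines 4 of 17 rose and 9 fell (camera adjusted p = 0.028, adjusted p = 0.292 with an estimated correlation): Cxcl2 fell by 2.49 ± 0.069 and Cxcl16 by 2.04 ± 0.043, and the interferon-gamma-induced Cxcl9, chosen after its values were seen, was 1.30 ± 0.115 higher on the log2 scale. Chemokine receptors fell in 9 of 13 cases and rose in 1, led by Ccr9 (−2.38 ± 0.055), Ccr2 (−2.16 ± 0.106) and Ccr7. All but 1 of 16 C-type lectin and Fc receptors fell, with Clec4d 15.3-fold lower, Clec4e at −2.35 ± 0.083 and Fcgr1 at −1.47 ± 0.163 (camera adjusted p = 6.03e-07). The receptor and lectin lists had adjusted p = 0.0652 with an estimated correlation.

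Cholesterol biosynthesis fell in 16 of 16 genes with butyrate as well (camera adjusted p = 3.11e-11, adjusted p = 0.0652 with an estimated correlation), and glycolysis rose in 9 of 12 and fell in 2 (0.0143, adjusted p = 0.399 with an estimated correlation). For glycolysis the median of 0.477 fell to 0.062 on the hybridization spike-in scale, where 5 rose and 3 fell. HDAC genes rose in 7 of 8 cases, led by Hdac1 (1.13 ± 0.052), although on the hybridization spike-in scale 4 of the 8 were called higher and 2 lower, with Hdac2 at −0.146 and Hdac3 at −0.134 (camera adjusted p = 0.00555, adjusted p = 0.0937 with an estimated correlation). Histone genes rose in 6 of 7 cases and fell in 1. H1f2 rose 5.96-fold and H2aw by 1.76 ± 0.055 on the log2 scale (camera adjusted p = 0.00439, adjusted p = 0.0937 with an estimated correlation), and on the hybridization spike-in scale 5 rose and 1 fell. Fatty acid oxidation genes rose in 10 of 18 cases and fell in 6 (camera adjusted p = 0.217), with a median of 0.416 that fell to 0.001 on the hybridization spike-in scale, where 7 rose and 8 fell. Class I presentation genes fell in 9 of 14 cases and rose in 0, with Psmb10 at −1.94 ± 0.060 (camera adjusted p = 0.000532, adjusted p = 0.161 with an estimated correlation), and of class II presentation genes 2 of 10 rose and 3 fell, or 2 and 8 on the hybridization spike-in scale (camera adjusted p = 0.217). Heat shock genes rose in 6 of 13 cases and fell in 4, and on the hybridization spike-in scale 2 rose and 9 fell (camera adjusted p = 0.839). The largest rises were in Selenom (7.48-fold), Fgf11 (6.36-fold), H1f2, Ckb (5.78-fold), Abhd3 (5.56-fold), the actin-severing gene Gsn (5.50-fold) and Ppp1r14a (5.45-fold). The metallothionein Mt2 rose 5.24-fold and Mt1 by 1.51 ± 0.058. Of 23 neuronal genes, which are repressed outside neurons, 13 were called higher and 0 lower with butyrate, and the list's median of 0.225 turned to −0.190 on the hybridization spike-in scale, where 2 were higher and 11 lower. Their camera adjusted p was 0.028, with adjusted p = 0.125 with an estimated correlation.

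Markers of other cell types fell with butyrate in 13 of 15 macrophage and monocyte genes (median −0.64), 6 of 8 erythroid genes (−0.70) and 6 of 10 neutrophil genes (−0.37; 7 adjusted over the list alone), with 0, 1 and 3 rising, beside the falls of immune genes. With an estimated correlation their adjusted p was 0.154, 0.193 and 0.274, against camera adjusted p of 5.72e-06, 0.00247 and 0.028. NK markers fell in 3 of 8 genes and rose in 1, led by Klrk1 (−2.58 ± 0.072) and Klrd1 (−1.88 ± 0.071), with a camera adjusted p of 0.0357 and adjusted p = 0.161 with an estimated correlation. B cell and T cell markers were not called as lists (adjusted p = 0.217 and 0.474), with 3 and 1 of 10 lower, although on the hybridization spike-in scale 9 of 10 were lower in each. Of CD11b-type DC markers 9 of 11 fell and 1 rose, or 9 and 2 adjusted over the list alone, and of plasmacytoid DC markers 7 of 8 fell and 1 rose. Their camera adjusted p was 0.0031 and 0.000532, and they had adjusted p = 0.125 and 0.0652 with an estimated correlation. Flt3 fell by 0.63 ± 0.045 and Itgax by 0.74 ± 0.061. None of the 22 lists that camera called for butyrate was called with an estimated correlation, whereas fry called 38 of 41. For TSA these counts were 28, 10 and 38. Some lost lists had estimates below the preset 0.01, such as chemokine receptors (−0.028) and Toll-like receptors (0.006) with butyrate. Their own correlation therefore does not explain the lost calls, and the reason was not tested.

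**Figure D3:**
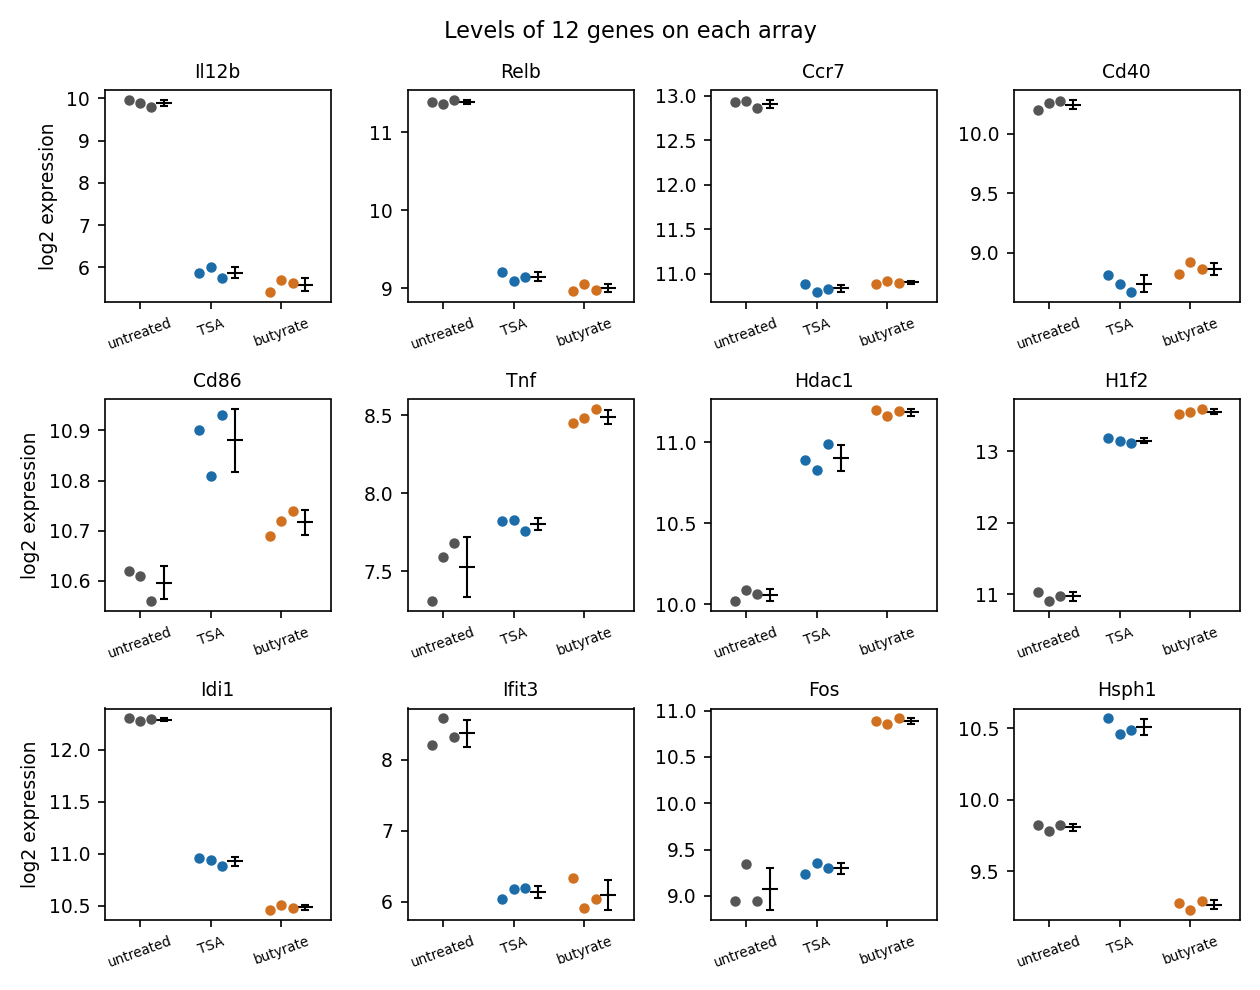
Log2 expression (y axis, a separate range for each gene) of 12 genes in untreated, TSA and butyrate samples (x axis); points are the 3 arrays of each group and the black marks are the mean ± SD. Il12b lies at 9.88 in untreated cells and at 5.88 and 5.59 after TSA and butyrate, and Hsph1 lies above the untreated arrays with TSA and below them with butyrate.

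The changes with TSA and butyrate were set side by side. Of the genes called, 2525 rose and 2204 fell with both treatments, 4729 in all, against 1743 that independent lists of these sizes would share. In 100 simulations of unchanged groups with shared controls 0 were shared, which says nothing of the overlap that shared controls give, since genes without effects are hardly called. On the hybridization spike-in scale the genes changed by both treatments in the same direction numbered 3213, and on the poly-A spike-in scale 1825. Opposite calls were made for 156 genes. The fold changes correlated across genes with r = 0.891, where the simulations without effects gave a mean of 0.499 because the untreated arrays are shared. Their covariance was 0.24 against a simulated 0.0031, a difference of 0.237. With 3 untreated arrays the controls could not be split into parts of at least 2, and part of the excess overlap may come from sharing them. Of the 4729 genes, 1980 differed between the treatments by the direct test, 1331 with the larger change under butyrate and 649 under TSA. This split holds for the deposited scale and was not counted on the spike-in scales. There the direct test over all genes called 93 higher and 10047 lower with butyrate (hybridization) and 19 and 2782 (poly-A).

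**Figure D4:**
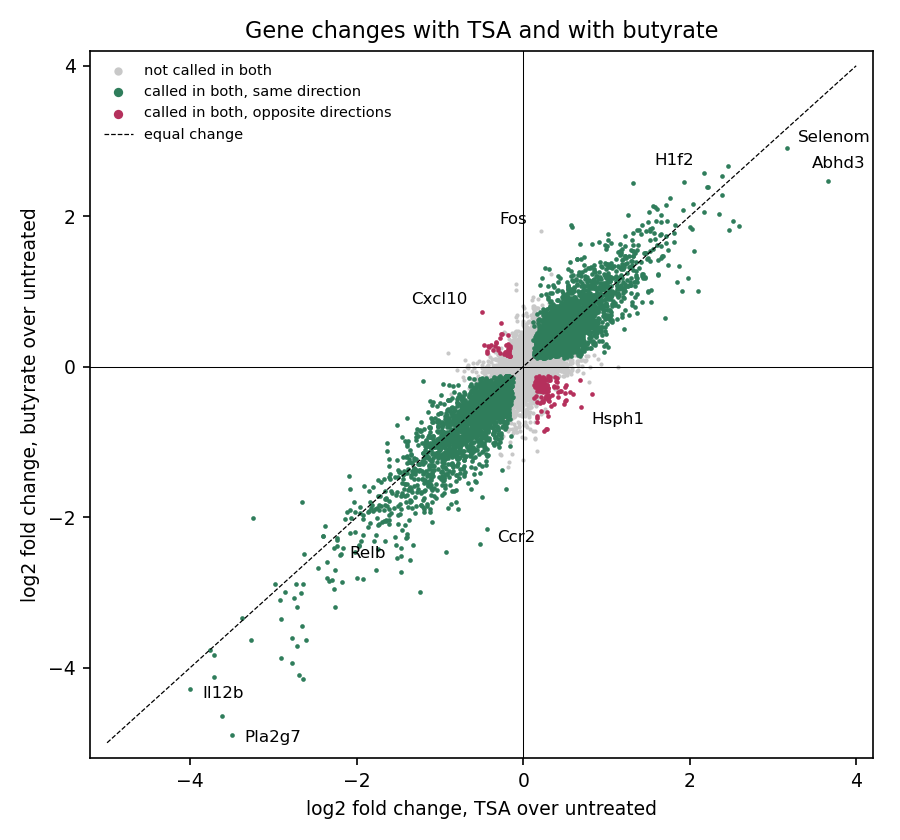
Log2 fold change of each of the 12393 genes with TSA (x axis) and with butyrate (y axis), both over untreated cells; green points were called in both in the same direction, red points in opposite directions and grey points were not called in both. The dashed line marks equal change, and there are 4729 green points, of which 1980 differed between the treatments by the direct test, and 156 red points.

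Butyrate and TSA were also set directly against each other. The transcription factor genes Fos and Nr4a1, which respond to signals within minutes, were 3.01-fold and 2.42-fold higher with butyrate than with TSA, and the decoy receptor Il1r2 2.49-fold and Cxcl10 2.32-fold higher. The lectin gene Clec4e was 3.56-fold lower with butyrate, Clec4b1 3.39-fold, the monocyte chemokine receptor Ccr2 3.29-fold, Ms4a6d 2.89-fold and Slc7a11 2.83-fold. The doses and times of both treatments are unknown here and may not match. In all, 1968 genes were higher and 2480 lower with butyrate than with TSA, 35.9% of those tested, of which 11 and 36 differed by at least 2-fold.

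Immediate early genes were higher with butyrate than with TSA in 8 of 15 cases and lower in 0 (camera adjusted p = 0.00106, adjusted p = 0.435 with an estimated correlation), with a median of 0.406 that fell to 0.006 on the hybridization spike-in scale, where 5 were higher and 7 lower. Against untreated cells 3 of them rose and 7 fell with TSA (median 0.052 but mean −0.178, camera adjusted p = 0.177). With butyrate 7 rose and 3 fell (camera adjusted p = 0.49), and 4 rose and 9 fell on the hybridization spike-in scale. Chemokines were higher in 8 of 17 cases and lower in 2, led by Cxcl10 (1.22 ± 0.111), Cxcl9 (0.99 ± 0.115) and Ccl22 (0.87 ± 0.053), with a median of 0.198 that turned to −0.203 on the hybridization spike-in scale. Their camera adjusted p was 0.0166, and adjusted p = 0.441 with an estimated correlation. Neutrophil markers were higher in 8 of 10 cases and lower in 1 (also 0.0166 and 0.441), with a median of 0.229 that turned to −0.171 on that scale. Cholesterol genes were lower with butyrate in 12 of 16 cases, with Cyp51 at −0.67 and Nsdhl and Sc5d at −0.56 each (camera adjusted p = 6.34e-06, adjusted p = 0.42 with an estimated correlation). Heat shock genes were lower in 10 of 13 cases, led by Hsph1 (−1.24 ± 0.047), Hspa4l (−0.74) and Hspa2 (−0.52), with a camera adjusted p of 3.61e-05 and adjusted p = 0.42 with an estimated correlation. Camera called these 5 of the 41 lists with the preset correlation and 0 lists with an estimated correlation.

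Some genes were not called between the treatments. Pdcd1lg2, chosen after its values were seen, was −0.01 on the log2 scale with butyrate relative to TSA, Rela 0.01 with a 95% interval from −0.094 to 0.110, Hdac3 −0.01 (−0.122 to 0.094) and Flt3 −0.03 (−0.135 to 0.068). None of these was called, and intervals for Cd40 (0.005 to 0.243) and Il6 (−0.72 to 0.017) were wider. Relb was slightly lower with butyrate (−0.14 ± 0.049), Tnf was higher (0.69 ± 0.084) and Cdkn1a, a cell cycle inhibitor, was higher (0.42 ± 0.052). On the hybridization spike-in scale the median difference of all genes was −0.367 in place of 0.033, and the split was 93 higher and 10047 lower (0.9% higher) in place of 44.2% higher. With poly-A spike-ins it was 19 and 2782 (0.7% higher). With only genes above the median level it was 1284 higher and 2405 lower.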

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

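The tests of the spike-ins, of the marker lists and of the covariance were chosen after the values were seen; the counts over other splits of the arrays were planned.

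TSA and butyrate changed 156 genes in opposite directions. Each also passed the direct test between the treatments, which adds no support, since opposite calls of this kind fix its outcome. TSA raised and butyrate lowered 114, among them the heat shock gene Hsph1, whose difference was −1.24 on the log2 scale (0.70 ± 0.047 with TSA, −0.54 ± 0.047 with butyrate). TSA lowered and butyrate raised 42, among them Cxcl10, whose difference was 1.22 (−0.49 ± 0.111 and 0.73 ± 0.111). On the hybridization spike-in scale 596 genes had opposite calls, and on the poly-A spike-in scale 7. Of the 2246 probe sets without a single gene name, which no gene-level comparison uses, 764 were called with TSA and 1098 with butyrate.

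Some control probe sets, which the comparisons of genes do not use, were brighter on the butyrate arrays than on the untreated ones. Others were not, such as those of beta-actin (−0.274 to −0.524). Hybridization spike-ins were higher by 0.415 ± 0.057 (SE, n = 3 each), and probe sets of 18S ribosomal RNA by 0.754 ± 0.161, and the 3 butyrate arrays lay above all 6 others in both. A smaller share of messenger RNA in the butyrate samples would raise the poly-A spike-ins, which are meant to be added before labelling, above the hybridization spike-ins, which are meant to be added after it. The poly-A spike-ins rose by 0.355 ± 0.187 (SE), and their rise minus that of the hybridization spike-ins was −0.06. Given this wide error, the value argues only weakly against a smaller share of messenger RNA as the whole cause. It also requires that the spike-ins were added as their design intends, which the labels do not state. The larger rise of the 18S probe sets (0.754 against 0.415) points the other way and was not tested. A difference in hybridization, loading or scanning is consistent with the rise of 0.415, but scan dates and batches, which would be needed to part it from butyrate itself, were not analysed here, and an effect of butyrate on the amount of RNA stays open.

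Markers of neutrophils and erythroid cells fell with TSA. The CD11c bead selection is meant to remove both cell types. A smaller share of such cells would lower all of a type's markers alike. That holds only if no other cells make these markers and the arrays measure every fold change in full. The log2 fold changes of the 9 neutrophil markers above the median array level had an SD of 0.658 against a median standard error of 0.060, from −2.14 for Camp to −0.10 for S100a9. For 8 erythroid markers the SD was 0.411 against 0.058, from −1.14 for Tspo2 to −0.18 for Alas2; S100a9 and Alas2 were chosen after their values were seen. Neither condition was tested, so the spread cannot decide whether a smaller share of neutrophils or erythroid cells is the whole cause. That share, other changes beside it and lower transcription within the cells stay open and were not tested.

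Parallel changes under both treatments could come from the shared untreated arrays. The covariance of 0.24 lies above the highest of 100 simulations without effects (0.0033). This argues against independent noise of the untreated arrays as the whole cause. A deviation common to all 3 untreated arrays would enter both comparisons, was not simulated and stays open. A shared response to HDAC inhibition is a hypothesis that these data do not test further, since no group received a compound that leaves HDACs alone. The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 5866 genes for TSA, 7241 for butyrate and 4448 for butyrate against TSA, each the 1 highest of its 10 splits. The highest of the other splits called 0 in every comparison. Every other split mixes arrays of both groups in each part, which adds the difference between them to the spread. The 0 is therefore not a count of calls without effects, and the contrast adds no support.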

How the results depend on the processing

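Tests on the 2 spike-in scalings were chosen after the data were seen, and all others were planned. The counts of called genes, of genes changed at least 2-fold, of shared calls and of called lists stayed within 1.5 times their values under the fit to 2 groups, the trend with robust variances, the filters, the mean of a gene's probe sets, the further quantile normalization, equal medians, array weights and each left-out array. Over the 9 left-out arrays the ranges were 5331 to 5865 genes for TSA, 6559 to 7205 for butyrate, 3397 to 4470 for butyrate against TSA, 651 to 689 and 901 to 921 genes changed at least 2-fold, 4343 to 4635 changed by both, 27 to 29, 21 to 22 and 5 to 7 called lists, and a covariance of 0.237 to 0.246. Same-numbered replicates of different groups did not deviate together (r from −0.12 to 0.21, and the best match had the same number in 5 of 18 cases). With the replicate block 5732, 7089 and 4116 genes were called, and 522 of 534 values of named genes kept direction and call. Testing every probe set called 9708, 12127 and 6692 probe sets, 1032 and 1430 of them changed at least 2-fold, and 7768 by both, because more features were tested; its covariance was 0.21. The covariance was 0.336 and 0.309 with genes above the median and the 25th percentile of level and 0.212 with the mean of probe sets, and the cause was not tested. An estimated correlation left 10, 0 and 0 called lists for TSA, butyrate and butyrate against TSA, and fry called 38 for butyrate and 25 for butyrate against TSA. Signal over background limits the calls of dim genes, whose values lie near the RMA floor.

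On the hybridization spike-in scale 10140 genes differed between butyrate and TSA and 1445 changed at least 2-fold with butyrate. On the poly-A scale 2529 genes were called for TSA, 4129 for butyrate, 2801 for butyrate against TSA and 1825 for both, with 9 lists called for butyrate against TSA. These values follow from the shift of the butyrate arrays and, for poly-A spike-ins, from their larger spread. With the mean of probe sets Bcl2l2 turned to 0.023 with butyrate and 0.126 for butyrate against TSA, since its probe sets disagree. On the hybridization spike-in scale the butyrate changes turned for Sirt7 (−0.094), Bsg (−0.261), Slc16a1 (−0.268), Cdkn2d (−0.014), Prf1 (−0.02), Gpr143 (−0.138), Pmel (−0.15), Slc45a2 (−0.176), Hdac2 (−0.146), Hdac3 (−0.134), Tgfb1 (−0.006), Cd80 (−0.231), Cd86 (−0.296) and Hcar2 (−0.329), and those of butyrate against TSA for Hdac5 (−0.115), Hdac1 (−0.12), Sirt4 (−0.176), H1f2 (−0.001), H2ax (−0.097), H2-Oa (−0.054), H2-DMa (−0.079), Tnip1 (−0.003), Myd88 (−0.043), Nlrp3 (−0.083), Pfkl (−0.116), Tpi1 (−0.165), Bcl2 (−0.145), Stmn4 (−0.025), Stmn3 (−0.087), Mt3 (−0.154), Atf4 (−0.064), Irf8 (−0.084), Clec10a (−0.089), C1qa (−0.148), Cd22 (−0.022), Ms4a1 (−0.148), Lat (−0.185), Mpo (−0.093), Alas2 (−0.005), Slc4a1 (−0.128), Tspo2 (−0.198), Pmel (−0.034), Sox10 (−0.237), Il12a (−0.301), Il10 (−0.374), Rela (−0.393), Tgfb1 (−0.303), Cd80 (−0.333), Cd40 (−0.277), Cd274 (−0.225), Ffar2 (−0.302), Slc5a8 (−0.353) and Itgax (−0.154). On the poly-A scale the butyrate changes turned for Sirt7 (−0.033), Bsg (−0.201), Slc16a1 (−0.208), Gpr143 (−0.078), Pmel (−0.09), Slc45a2 (−0.116), Hdac2 (−0.086), Hdac3 (−0.074) and Cd80 (−0.17), and those of butyrate against TSA for Hdac5 (−0.043), Hdac1 (−0.048), Sirt4 (−0.104), H2ax (−0.025), H2-DMa (−0.007), Nlrp3 (−0.011), Pfkl (−0.044), Tpi1 (−0.093), Bcl2 (−0.073), Stmn3 (−0.015), Mt3 (−0.082), Irf8 (−0.011), Clec10a (−0.017), C1qa (−0.075), Ms4a1 (−0.076), Lat (−0.113), Mpo (−0.02), Slc4a1 (−0.056), Tspo2 (−0.126), Sox10 (−0.165) and Itgax (−0.082). The left-out arrays turned 0 of 4806 values of named genes and ended the call of 156.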

Other observations

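The tests below are the gene list tests fixed before the data were examined. Of 25 cell cycle genes, 5 rose and 13 fell with TSA and 5 rose and 10 fell with butyrate (camera adjusted p = 0.0549 and 0.154); on the hybridization spike-in scale 0 rose and 20 fell with butyrate. Mki67 fell with both (−0.55 ± 0.043 and −0.65 ± 0.043), and the replication helicase genes Mcm6 (0.88 ± 0.053 and 0.57 ± 0.053) and Mcm2 (0.63 ± 0.071 and 0.58 ± 0.071) rose. Among inhibitors of cyclin-dependent kinases, Cdkn2b fell by 2.35 ± 0.084 and 2.81 ± 0.084 and Cdkn1c rose by 0.81 ± 0.132 and 0.72 ± 0.132. Cdkn1a (p21), a gene often raised by HDAC inhibitors, fell by 0.59 ± 0.052 with TSA and by 0.17 ± 0.052 with butyrate. In the BCL2 family 2 of 13 rose and 5 fell with TSA and 4 rose and 7 fell with butyrate, with Bak1 down by 1.11 ± 0.050 and 1.31 ± 0.050 and Bid up by 0.66 ± 0.059 and 0.71 ± 0.059. Of 15 genes of the unfolded protein and integrated stress responses 2 rose and 7 fell with TSA (camera adjusted p = 0.0245, adjusted p = 0.0996 with an estimated correlation), with Herpud1 at −1.12 ± 0.047 and Atf3 at −0.98 ± 0.061.

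Among genes of regulatory DC, Ido1, which degrades tryptophan, fell by 2.65 ± 0.127 with TSA and 2.89 ± 0.127 with butyrate, Il1rn by 1.59 ± 0.091 and 1.65 ± 0.091, and the retinoic acid enzyme gene Aldh1a2 by 0.43 ± 0.077 and 0.71 ± 0.077. Tgfb1 rose by 0.31 ± 0.047 and 0.41 ± 0.047, the latter turning to −0.006 on the hybridization spike-in scale. Of the 17 genes 4 rose and 9 fell with TSA (camera adjusted p = 0.0137, adjusted p = 0.0996 with an estimated correlation) and 6 rose and 7 fell with butyrate (0.139), or 2 and 12 on the hybridization spike-in scale. Among 18 DC transcription factors 2 rose and 10 fell with TSA and 5 rose and 10 fell with butyrate (camera adjusted p = 0.00208 and 0.0489, with adjusted p = 0.0453 and 0.161 with an estimated correlation), led by Zeb2 (−1.47 ± 0.200 and −2.51 ± 0.200) and Spi1 (−0.97 ± 0.050 and −1.45 ± 0.050). Of the receptors that sense butyrate, Ffar2 fell by 0.47 ± 0.077 and 0.37 ± 0.077, and Hcar2 and the transporter Slc5a8 were not called in any comparison. Slc5a8 averaged 4.1 over all arrays, near the floor, where a change could go unseen.

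List tests of TSA or butyrate that are not given above were not called by camera, except those of the cytokine and growth factor receptors of DC. Of these 19 receptors 4 rose and 11 fell with TSA (camera adjusted p = 0.0036, adjusted p = 0.224 with an estimated correlation) and 7 rose and 10 fell with butyrate (0.028, and adjusted p = 0.399 with an estimated correlation), and the butyrate counts became 1 and 15 on the hybridization spike-in scale, with Csf2ra down by 1.93 ± 0.063 and 2.03 ± 0.063. Of 8 inflammasome and NOD-like receptor genes 3 rose and 3 fell with TSA and 4 rose and 4 fell with butyrate (0.863 and 0.456). Of 7 short-chain fatty acid receptors and transporters 2 rose and 1 fell, then 2 and 2 (0.779 and 0.587). Of 11 histone acetyltransferases and bromodomain readers 1 rose and 4 fell, then 3 and 7 (0.151 and 0.164). Of 5 metallothioneins and zinc transporters 2 rose and 3 fell, then 2 and 2 (0.779 and 0.995), with a TSA median of −0.229 but a mean of 0.219. Of 7 CDK inhibitors 2 rose and 3 fell with each treatment (0.392 and 0.358), with a TSA median of 0.015 but a mean of −0.278. Sirtuins rose in 4 of 5 cases and fell in 1 with butyrate (0.217), with a median of 0.322 that turned to −0.094 on the hybridization spike-in scale. For the BCL2 family the camera adjusted p was 0.0583 and 0.217, for CD8-type DC with butyrate (4 of 10 up, 5 down) 0.167, for the stress response with butyrate (5 of 15 up, 6 down) 0.358, for neuronal genes with TSA (6 of 23 up, 0 down) 0.258, and for B16 markers 0.779 and 0.886.

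Other butyrate counts also moved on the hybridization spike-in scale. There 1 of the 13 costimulatory and coinhibitory ligands rose and 11 fell, 2 of 17 chemokines rose and 13 fell, 2 of 18 DC transcription factors rose and 14 fell, and 0 of the NF-kB genes rose and 12 of 15 fell. For inflammasome genes the counts were 1 up and 5 down of 8, for short-chain fatty acid genes 0 and 7 of 7, for histone acetyltransferases and bromodomain readers 2 and 8 of 11, for CDK inhibitors 1 and 5 of 7, for metallothioneins and zinc transporters 2 and 3 of 5, and for the BCL2 family 1 and 9 of 13. For the stress response they were 0 and 10 of 15, for CD8-type DC 0 and 6 of 10, for NK cells 0 and 7 of 8, for neutrophils 0 and 10 of 10, and for B16 markers 0 and 6 of 9.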
